A study of Mus musculus with 16 samples.

How the data were processed

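RNA sequencing of polyadenylated RNA was carried out on 2 immortalized mouse epicardial cell lines, 1 with intact Tgfbr3 (wt) and 1 with Tgfbr3 knocked out on both alleles (mt). Each line received vehicle, TGFB1, TGFB2 or BMP2, in duplicate, which gives 8 groups of 2 libraries and 16 libraries in all. The epicardium is the outer cell layer of the heart, and immortalization rested on a temperature-sensitive T antigen that is active at the growth temperature of 33 °C and not at the 37 °C of the experiment. Per the labels, 200000 cells per well were incubated for 72 h with 250 pM TGFB1, 250 pM TGFB2 or 5 nM BMP2.

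The authors deposited 2 tables, 1 for each replicate number, with the same 30385 gene entries and positions in both. For each library the deposited values are counts, that is raw reads per gene, and rpm, that is reads scaled to a total of 1e+06 over the listed genes. The deposited rpm matched the reads divided by the column total to within 2.9e-11. Reads had been aligned with TopHat or TopHat2 to genome build mm9 per the submitters' processing notes, which give no version. The counting program, gene models, strandedness and treatment of reads that map to several places were not given in the sources used here. In the table for replicate number 2, 2 entries without a gene name, holding the column totals and 1 stray value, were left out. A date-like form was found in 27 gene names of each table; these were kept but not named here. Of the gene entries tested, 1485 shared a locus with another entry, so 16835 entries stand for 16053 distinct loci. Positions are those of build mm9 as deposited.

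Library totals ran from 6410320 to 31813921 reads. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, robust quasi-likelihood fit with 8 group means, quasi-likelihood F test), with Benjamini-Hochberg adjustment over the 16835 genes that passed the filter and a threshold of 0.05 on the adjusted p. The fit left 8 residual degrees of freedom, and the biological coefficient of variation was 0.274. Log2 fold changes are given with a standard error (SE) derived from the test: the absolute log2 fold change over the square root of F. Intervals of the ligand difference rest on this SE. Levels are given as TMM-scaled counts per 1e+06 reads (CPM). Comparisons were each ligand against vehicle within each line, TGFB2 against TGFB1 within each line, mt against wt in vehicle and averaged over the 4 treatments, and the difference of each ligand's effect between the lines (interaction). For groups with 0 reads, a fold is a lower bound against a floor of 3 reads over the group; for groups with 1 to 3 reads the ratio of the groups' reads is given with its exact 95% binomial counting interval, which covers counting error only.

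A set of 28 gene lists was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison; tests were repeated with an estimated correlation. The groups, comparisons, tests, lists and naming rule were fixed before the data were examined. The rule names Tgfbr3, 18 anchor genes of TGF-beta, BMP and epicardial biology, the 6 largest rises and 6 largest falls of a comparison among called genes with a mean of at least 5 CPM that changed the same way in both same-numbered pairs, and the 2 to 4 called members of each list with the smallest p. Genes named outside the rule are identified as such, and 1 gene that the rule names is not reported here.

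The replicate numbers pair the samples. After removal of the group means, libraries of the same number correlated above 0.1 in 28 of 28 pairs of groups (lowest 0.16, median 0.51, highest 0.76), and each number has its own table. The test without a replicate term had been fixed and was kept; the same test with the replicate number as a term is called blocked, and its coefficient of variation was 0.17. The alternatives fixed beforehand were RLE size factors in the edgeR fit, no low-count filter, the block and the DESeq2 1.42.0 Wald test. Also fixed were the compared groups alone, each library left out in turn, and the estimated correlation. Chosen after seeing the data were counts without the X and Y chromosomes, without chromosome 8, with shared loci counted once, and without the 4 mt replicate 1 libraries.

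The tests were tried on simulated data with 200 genes changed in each comparison, 50 at each of 4 sizes. The changed genes were drawn from those with a mean of at least 5 CPM. For a ligand against vehicle with BMP2 in wt cells, 6 of 50 genes changed 2-fold and 39 of 50 changed 4-fold were recovered, and none of those changed 1.5-fold (0 of 50). For the interaction with TGFB1, 0 of 50 changed 2-fold, 15 of 50 changed 4-fold and 40 of 50 changed 8-fold were recovered. There was 1 line per genotype, so genotype, clone and sex cannot be told apart, and the labels do not say whether replicates were separate cultures; p values measure the spread between these samples. Figures were drawn with matplotlib.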

Results

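Gene expression was measured by RNA sequencing in 16 libraries from 2 immortalized epicardial lines, wt and mt, that were isolated from mouse embryos at E11.5. The lines differ in the targeted gene Tgfbr3 and, by their Xist and Y-linked transcripts, in sex. Each line was given vehicle, TGFB1, TGFB2 or BMP2 for 72 h, with 2 libraries per group. Depth is given in units of 1e+06 reads, for replicates 1 and 2. The wt vehicle libraries held 21.89 and 27.22, those with TGFB1 17.0 and 31.81, with TGFB2 16.7 and 23.26, and with BMP2 6.41 and 17.9. The mt vehicle libraries held 12.01 and 18.59, those with TGFB1 13.42 and 29.5, with TGFB2 12.99 and 29.35, and with BMP2 7.11 and 24.43. Unless stated otherwise, each value is a log2 fold change ± SE with n = 2 libraries per group, and adjusted p is that of the edgeR quasi-likelihood test over 16835 genes.

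Tgfbr3, the co-receptor that presents TGF-beta ligands to the signalling receptors, lies on chromosome 5 from 107535588 to 107718614. Its level in vehicle was 85.7 ± 20.7 CPM (SD, n = 2) in wt cells and 16.4 ± 2.56 CPM in mt cells, a 5.22-fold difference (-2.39 ± 0.32, adjusted p = 0.0019). The mt libraries held 70 to 348 reads of the gene, and which part of it the null allele lacks is not given in the sources used here. In wt cells Tgfbr3 fell with TGFB2 (-1.04 ± 0.30, adjusted p = 0.031). With TGFB1 its value was -0.89 ± 0.30 (adjusted p = 0.059, blocked 0.0037). The plot of CPM per library shows Tgfbr3 beside 6 responsive genes.

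**Figure D1:**
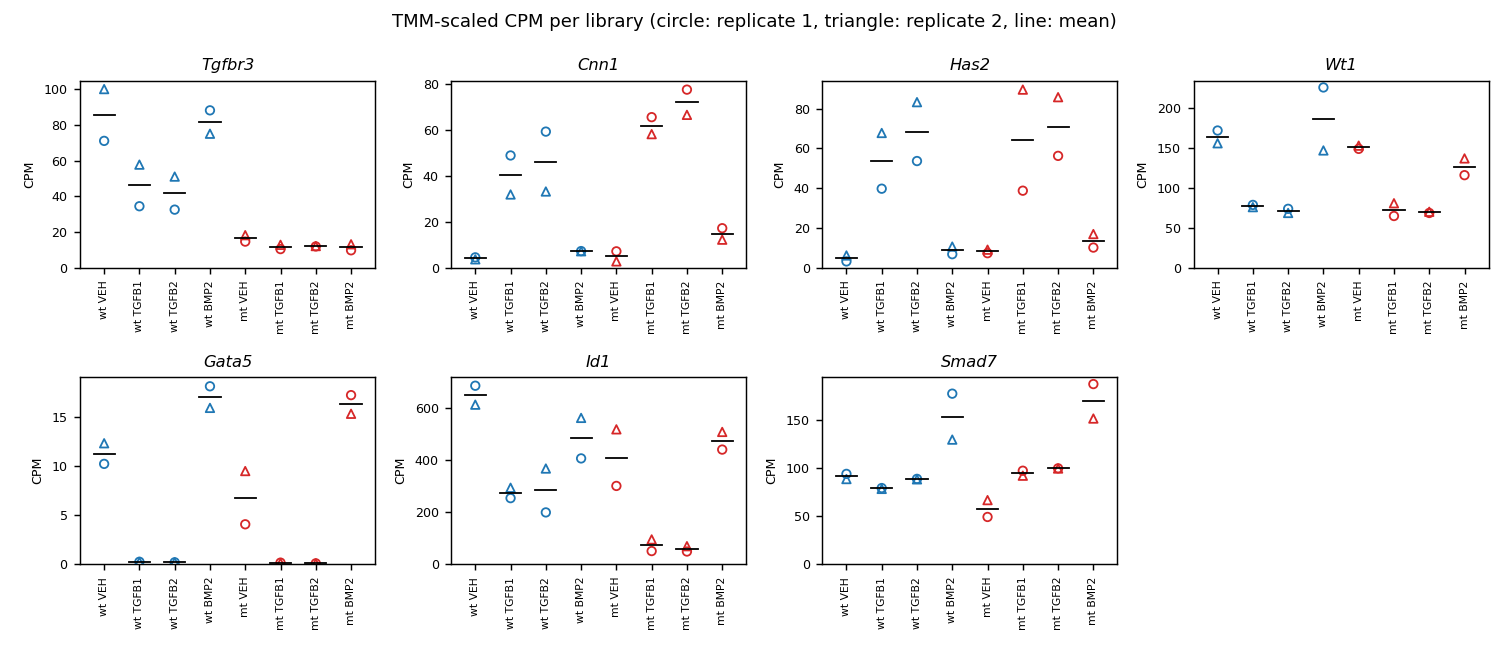
TMM-scaled CPM of 7 genes in each library on a linear axis from 0, by line and treatment (wt blue, mt red); circles are replicate 1, triangles replicate 2, and bars the mean of the 2. Tgfbr3 lies between 9.73 and 18.2 CPM in all mt libraries, and Cnn1 is at or above 31.9 CPM in every TGFB1 or TGFB2 library.

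The ligand comparisons asked how wt epicardial cells answer TGFB1 and TGFB2. The smooth muscle gene Cnn1 rose by 3.31 ± 0.43 with TGFB1 and 3.51 ± 0.43 with TGFB2, and the hyaluronan synthase Has2 by 3.52 ± 0.51 and 3.87 ± 0.52. The epicardial transcription factor genes Gata5 (-5.61 ± 0.43 and -5.92 ± 0.45) and Wt1 (-1.08 ± 0.22 and -1.20 ± 0.22) fell with TGFB1 and TGFB2. TGFB1 changed 3203 genes (1821 higher, 1382 lower) and TGFB2 changed 3383 (1862 higher, 1521 lower); each called gene had the same sign in both same-numbered pairs. The blocked test called 5630 and 5837 genes, and the fit with only the groups compared 3258 and 3552. Leaving out any 1 of the 4 libraries compared left 1575 (without wt vehicle replicate 2) to 1906 (without wt vehicle replicate 1) genes for TGFB1, and 1775 to 2087 for TGFB2 with the same libraries left out.

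The genes with the largest rises in wt cells were Acsbg1, Col11a1, Cpne7, Fzd10, Ctsw and, for TGFB1, Fam159b (6.23 ± 0.63) or, for TGFB2, Tnfrsf11b, the decoy receptor osteoprotegerin (6.60 ± 0.46). Acsbg1 had 0 reads in wt vehicle and was at least 70.3-fold higher with TGFB1 and at least 108-fold higher with TGFB2. Col11a1, a fibrillar collagen chain of cartilage, rose by 7.12 ± 0.66 and 7.33 ± 0.67, and Ctsw by 6.45 ± 0.53 and 6.84 ± 0.54. Cpne7 had 2 reads in wt vehicle, a ratio of 129 with TGFB1 (95% counting interval 35.2 to 1070) and 123 with TGFB2 (33.7 to 1030). The Wnt receptor gene Fzd10 had 3, with ratios of 121 (41.1 to 591) and 118 (40.1 to 578). The largest falls were those of Stc1 (-6.37 ± 1.20 with TGFB1, -6.54 ± 1.23 with TGFB2), Aldoc (-5.85 ± 0.51, -5.99 ± 0.52), Gpr133 (-5.60 ± 0.85, -6.07 ± 0.89) and Dlk1 (-5.19 ± 0.44, -5.26 ± 0.44), with Gata5, Lgals2 for TGFB1 (-4.96 ± 0.68) and Col6a2 for TGFB2 (-4.82 ± 0.39).

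More epicardial and mesothelial genes fell than rose in wt cells. Of 28 tested, 17 fell and 1 rose with TGFB1 (21 and 2 adjusted over the list alone), and 17 fell and 2 rose with TGFB2 (20 and 2 adjusted over the list alone). Podxl (-3.92 ± 0.37 and -4.62 ± 0.39) and the mesothelial uroplakin gene Upk3b (-2.24 ± 0.25 and -2.34 ± 0.25) were among them. The list test gave adjusted p = 2e-09 with TGFB1 (adjusted p = 0.06 with an estimated correlation) and 1.1e-09 with TGFB2 (adjusted p = 0.044 with an estimated correlation). Of 29 TGF-beta and SMAD3 targets, 14 rose and 2 fell with TGFB1, the same counts adjusted over the list alone; 15 rose and 3 fell with TGFB2 (17 and 3 adjusted over the list alone). Ctgf rose by 2.55 ± 0.30 and 2.70 ± 0.30 and Pmepa1 by 3.75 ± 0.45 and 3.72 ± 0.45. Its adjusted p was 4.2e-05 with TGFB1 (adjusted p = 0.06 with an estimated correlation) and 7.5e-06 with TGFB2 (adjusted p = 0.044 with an estimated correlation). BMP and SMAD1/5 targets went the other way: 10 of 22 fell and 1 rose with TGFB1 (11 and 2 adjusted over the list alone, 12 and 5 in the blocked test). Smad9 (-3.09 ± 0.33), Smad6 (-2.51 ± 0.31), Atoh8 (-2.47 ± 0.30) and the inhibitor of differentiation Id1 (-1.25 ± 0.39) fell. That list had an adjusted p of 0.00093 (adjusted p = 0.11 with an estimated correlation) with TGFB1 and 0.0019 (adjusted p = 0.13 with an estimated correlation) with TGFB2, where 11 fell and 1 rose by either adjustment, over all genes and adjusted over the list alone.

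Matrix and contractile genes split in wt cells. Of 24 collagens, 12 rose and 5 fell with TGFB1 (15 and 5 adjusted over the list alone); Col4a4 rose by 2.47 ± 0.28, while Col6a1 and Col6a2 fell (-3.64 ± 0.34 and -4.61 ± 0.38). Of 35 hyaluronan and matrix remodelling genes, 16 rose and 3 fell with TGFB1 (17 and 3 adjusted over the list alone), with Mmp10 at 5.74 ± 0.67, Hyal1 at 3.22 ± 0.37 and Plod2 at 2.18 ± 0.23. The collagens had an adjusted p of 0.00093 (adjusted p = 0.37 with an estimated correlation) and the remodelling genes one of 6.4e-05 (adjusted p = 0.088 with an estimated correlation). Of 24 smooth muscle contractile genes, 8 rose and 3 fell with TGFB1 (11 and 3 adjusted over the list alone, 14 and 3 in the blocked test): Acta2 rose by 2.30 ± 0.52, whereas Mylk and Mrvi1 fell (-1.88 ± 0.36 and -1.5 ± 0.34), with an adjusted p of 0.014 (adjusted p = 0.56 with an estimated correlation). Tagln stood at 1.63 ± 0.58 (adjusted p = 0.071, blocked 0.0013). Among 34 matrix glycoproteins and proteoglycans, 7 rose and 8 fell (8 and 10 adjusted over the list alone), with Mfap4 at 4.35 ± 0.33, Postn at 4.04 ± 0.46 and Lama4 at -2.80 ± 0.36. The test of that list pointed down (adjusted p = 0.86, 0.94 with an estimated correlation) where its median of 0.17 and mean of 0.19 were positive.

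Mitotic, p53 and sterol genes were among those that TGFB1 changed in wt cells. Of 30 mitotic genes 12 fell and 0 rose (17 and 0 adjusted over the list alone, 26 and 0 in the blocked test), such as Cenpf (-2.06 ± 0.51), Ccnb2 (-1.53 ± 0.38) and Kif23 (-1.35 ± 0.27). Of 35 S phase and E2F targets 2 fell and 0 rose (0 and 0 adjusted over the list alone, 9 and 2 in the blocked test, list test adjusted p = 0.17). Of 30 p53 targets 16 rose and 0 fell (21 and 1 adjusted over the list alone), among them Perp (4.01 ± 0.46), Fas (1.93 ± 0.27) and Tnfrsf10b (1.69 ± 0.22). Of 25 cholesterol synthesis genes 11 fell (15, with 1 risen, adjusted over the list alone, and 16 with 1 in the blocked test), including Sqle (-1.58 ± 0.25) and Hmgcs1 (-1.39 ± 0.23). Their adjusted p values were 1.5e-07 for mitosis, 1.1e-08 for p53 and 4.2e-05 for cholesterol. None of the 3 held otherwise: adjusted p = 0.24 with an estimated correlation for mitosis, adjusted p = 0.11 with an estimated correlation for p53, and adjusted p = 0.06 with an estimated correlation for cholesterol. The interleukin gene Il6 rose by 4.83 ± 0.49 with TGFB1 and 5.50 ± 0.49 with TGFB2, while the chemokine gene Ccl2 fell with TGFB1 (-2.79 ± 0.50); across 36 NF-kappaB targets 7 rose and 9 fell (7 and 11 adjusted over the list alone; list test adjusted p = 0.33). Of 40 interferon-stimulated genes 7 fell and 0 rose (7 and 1 adjusted over the list alone, 11 and 3 in the blocked test), with Oas2 at -2.30 ± 0.45 (-1.48, adjusted p = 0.053, without wt vehicle replicate 2). That list's adjusted p was 0.026 (adjusted p = 0.56 with an estimated correlation).

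The 2 TGF-beta ligands gave largely overlapping lists in each line. In wt cells 2839 genes were called for both ligands in the same direction (1616 higher, 1223 lower) and 0 in opposite directions, by edgeR. Independent lists of these sizes would share 201 and 125 genes. Both contrasts use the same 2 vehicle libraries, so part of the excess may come from these. In 10 simulations of unchanged ligand groups against shared vehicle libraries the overlap was 0; groups without change give few calls, so this value does not bound that part. The correlation across genes, which are not independent replicates, was 0.95 against 0.48 simulated, and the covariance 1.38 against 0.13. Parting the 2 vehicle libraries would leave 1 for each ligand, and this was not done. In mt cells 2520 genes were shared (1212 higher, 1308 lower; independent lists 110 and 132; 0 simulated), with a correlation of 0.96 against 0.53 and a covariance of 1.21 against 0.15.

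TGFB2 set directly against TGFB1 separated no gene in wt cells. The edgeR test called 0 genes (55 at an unadjusted p under 0.05; blocked 0 with 318; DESeq2 0). In mt cells it also called 0 (64; blocked 0 with 98; DESeq2 0). The median absolute log2 difference between the ligands was 0.17 in wt and 0.10 in mt cells. Its 95% interval lay within 2-fold for 9237 genes (54.9%) in wt and 10315 (61.3%) in mt cells, and within 4-fold for 15494 (92%) and 15660 (93%). Of 50 simulated genes with a 2-fold ligand difference 6 were recovered in either line, and of 50 with a 4-fold difference 36 in wt and 40 in mt, so differences of 2-fold were seldom detected here. Cnn1 stood at 40.4 ± 12 CPM with TGFB1 and 46.2 ± 18.4 with TGFB2 (SD, n = 2) in wt cells, and Il6 at 4.09 ± 1.55 and 6.44 ± 0.263.

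The mt cells, which lack intact Tgfbr3, were treated in the same way. With TGFB1 and TGFB2, Cnn1 rose by 3.67 ± 0.44 and 3.89 ± 0.44, and Has2 by 2.97 ± 0.50 and 3.12 ± 0.51. Id1 (-2.50 ± 0.41 and -2.81 ± 0.41), Id3 (-2.61 ± 0.80 and -2.86 ± 0.81) and the receptor gene Tgfbr2 (-0.90 ± 0.17 and -0.89 ± 0.17) fell, and Smad7, the inhibitor of the pathway, rose (0.71 ± 0.21 and 0.79 ± 0.21). Without mt vehicle replicate 2, Id3 was at -1.41 (adjusted p = 0.26) and -1.66 (0.19). TGFB1 changed 2763 genes (1341 higher, 1422 lower) and TGFB2 2933 (1376 higher, 1557 lower), with 5472 and 5641 in the blocked test. Without the 4 mt replicate 1 libraries, which hold cardiomyocyte transcripts, the counts were 1594 and 1637. The lowest leave-one-out counts were 1198 without mt TGFB1 replicate 2 and 1325 without mt TGFB2 replicate 2, and with only the groups compared 297 and 1064 genes were called.

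The largest rises in mt cells were those of Acsbg1, Crabp1, Col11a1, Tnfrsf11b, Zdhhc2 and, for TGFB1, Ctsw (4.92 ± 0.52) or, for TGFB2, Fam159b (4.92 ± 0.53). The retinoic acid binding protein gene Crabp1 rose by 6.36 ± 0.45 and 6.71 ± 0.45, Col11a1 by 6.16 ± 0.63 and 6.47 ± 0.64, Tnfrsf11b by 5.19 ± 0.40 and 5.33 ± 0.40, and Zdhhc2 by 4.75 ± 0.68 and 5.00 ± 0.68. Acsbg1 had 3 reads in mt vehicle, and its ratio was 149 with TGFB1 (95% counting interval 50.8 to 726) and 159 with TGFB2 (54.1 to 772). Among the falls were Saa3, an acute-phase serum amyloid gene (-6.82 ± 0.94 with TGFB1; 2 reads with TGFB2, a ratio of vehicle to TGFB2 of 452, interval 125 to 3740), Ccbe1 (-6.21 ± 0.67, -6.37 ± 0.68) and Angptl7 (-5.92 ± 0.78, -6.24 ± 0.80). Gata5 fell by 5.72 with TGFB1 (SE 0.48) and had 3 reads with TGFB2, a ratio of 101 (interval 34 to 491). Lrrtm3 (-5.74 ± 1.09) and Dlg2 (-5.34 ± 0.82) fell with TGFB1, and Vtcn1 (-5.92 ± 0.82) and Stc1 (-6.19 ± 1.5; -3.66, adjusted p = 0.16, without mt vehicle replicate 2) with TGFB2.

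Of the 28 epicardial and mesothelial genes, 20 fell and 1 rose in mt cells with TGFB1 (21 and 1 adjusted over the list alone) and 21 fell and 1 rose with TGFB2 by either adjustment, over all genes and adjusted over the list alone. Upk3b (-3.05 ± 0.26 and -3.43 ± 0.26), Podxl (-4.53 ± 0.39 and -4.67 ± 0.40) and Lrrn4 (-4.01 ± 0.39 and -4.22 ± 0.39) were the examples. The list test gave 3.3e-13 and 1.4e-13, and it held as adjusted p = 0.027 with an estimated correlation for TGFB1 and adjusted p = 0.025 with an estimated correlation for TGFB2. Among SMAD3 targets 15 rose and 4 fell with TGFB1 (17 and 6 adjusted over the list alone), including Fstl3 (3.19 ± 0.36) and Ltbp2 (3.02 ± 0.40), with an adjusted p of 0.00056 (adjusted p = 0.11 with an estimated correlation). Among BMP targets 10 fell and 1 rose (10 and 3 adjusted over the list alone), including Atoh8 (-4.51 ± 0.34) and Smad9 (-3.54 ± 0.36), with an adjusted p of 0.023 (blocked 0.053; adjusted p = 0.56 with an estimated correlation). Interferon-stimulated genes fell in 11 cases and rose in 0 (14 and 0 adjusted over the list alone), such as Ifit3 (-2.65 ± 0.45) and Gbp2 (-2.11 ± 0.35), with an adjusted p of 0.00067 (adjusted p = 0.67 with an estimated correlation).

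Smooth muscle genes gave 2 risen and 4 fallen of 24 in mt cells with TGFB1 (4 and 4 adjusted over the list alone, 9 and 4 in the blocked test; list test adjusted p = 0.13), with Acta2 at 1.44 ± 0.51 (adjusted p = 0.075, blocked 0.0041). Of 30 mitotic genes only Anln (-1.0 ± 0.23) and Kif23 (-0.86 ± 0.27) fell (1 adjusted over the list alone), with a list adjusted p of 0.006 (adjusted p = 0.67 with an estimated correlation), and the blocked test called 14. Of 30 p53 targets 10 rose and 1 fell (11 and 1 adjusted over the list alone), with Mdm2 at 1.79 ± 0.35 (1.08, adjusted p = 0.06, without mt TGFB1 replicate 2) and Sesn1 at -1.24 ± 0.25, and an adjusted p of 0.0017 (adjusted p = 0.67 with an estimated correlation). Of 24 collagens 7 rose and 5 fell (10 and 6 adjusted over the list alone; list test adjusted p = 0.42), with Col6a2 (-3.91 ± 0.37) and Col6a1 (-3.47 ± 0.34) among the latter. The growth factor receptor gene Pdgfra fell (-4.56 ± 0.61), while Vegfc (1.93 ± 0.22) and Nrp1 (2.17 ± 0.21) rose. Across genes the TGFB1 effects in the 2 lines correlated at 0.78 and the TGFB2 effects at 0.81. For TGFB1, 1909 genes were called in both lines in the same direction, 1 in opposite directions, and independent lists would share 262; for TGFB2 these were 2093, 3 and 293.

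**Figure D2:**
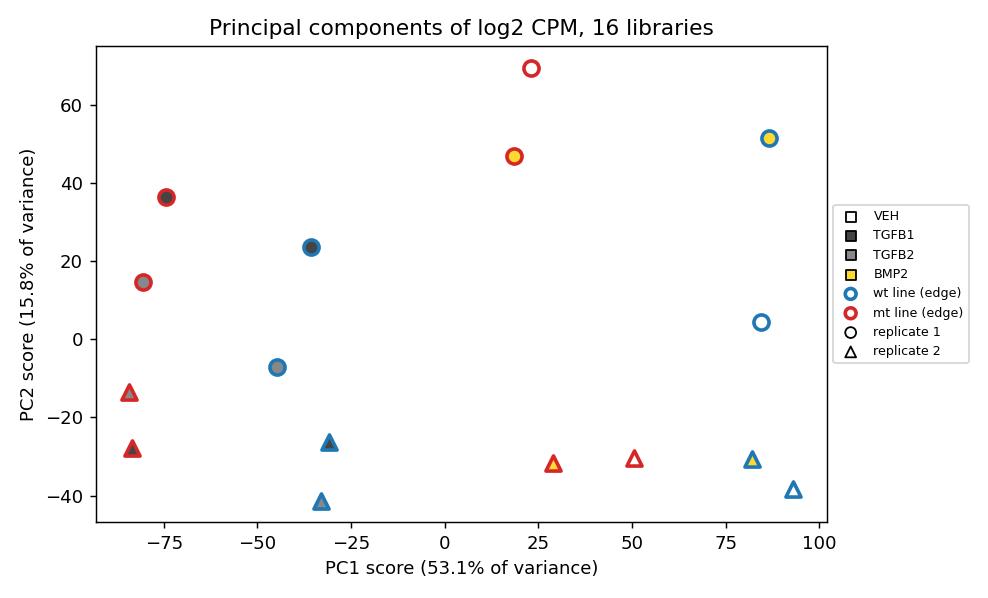
Principal component scores of log2 CPM for the 16 libraries, PC1 (53.1% of variance) against PC2 (15.8%), with line as edge colour, treatment as fill and replicate number as shape. On PC1 the wt TGFB1 and TGFB2 libraries lie between -44.8 and -30.8, the mt ones between -84.3 and -74.4, and every vehicle or BMP2 library is at or above 18.5.

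The BMP2 comparisons asked how each line answers a BMP ligand. In mt cells BMP2 raised Dlx3, a homeobox target of BMP signalling (3.91 ± 0.51, adjusted p = 0.019), Crabp1 (3.65 ± 0.46, 0.019), the cardiac T-box gene Tbx20 (1.66 ± 0.24, 0.04) and Smad7 (1.55 ± 0.22, 0.034), and lowered Dtx4 (-1.41 ± 0.18, 0.019). Of the 7 genes called, Lce1g (4.58 ± 0.53) and Lrrtm1 (-3.02 ± 0.35) fall outside the naming rule and were named after their values were seen. The count was 39 in the blocked test, 47 with DESeq2 and 0 with only the groups compared. None of the 7 kept its call when any 1 of the 4 libraries (mt BMP2 and mt vehicle, replicates 1 and 2) was left out. The same held without the mt replicate 1 libraries. Each of these fits leaves 1 library in a compared group. Of 22 BMP and SMAD1/5 targets 2 rose and 0 fell (5 and 0 adjusted over the list alone, 4 and 0 in the blocked test), and the list test gave 3.2e-11 (adjusted p = 0.015 with an estimated correlation). Of 29 SMAD3 targets Smad7 rose (3 adjusted over the list alone, 2 in the blocked test), with a list adjusted p of 8.5e-06 (adjusted p = 0.039 with an estimated correlation).

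In wt cells edgeR called 0 genes with BMP2 (867 at an unadjusted p under 0.05; blocked 0 with 2362; DESeq2 14). Dlx3 stood at 1.54 ± 0.39, Smad7 at 0.75 ± 0.21, Ltbp1 at 1.5 ± 0.26, Cd44 at 1.32 ± 0.30 and Ankrd1 at 2.10 ± 0.51, each with an adjusted p of 0.91. Tbx20 was 140 ± 7.12 CPM in vehicle and 327 ± 94 with BMP2 (SD, n = 2). No BMP or SMAD3 target passed over all genes, and 2 of 22 and 6 of 29 did adjusted over the list alone. The list tests pointed up for BMP targets (adjusted p = 0.0033, adjusted p = 0.26 with an estimated correlation), SMAD3 targets (adjusted p = 1e-05, adjusted p = 0.069 with an estimated correlation) and YAP and SRF targets (adjusted p = 6.2e-05, adjusted p = 0.42 with an estimated correlation). The wt BMP2 replicate 1 library was the shallowest, with 6410320 reads.

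The lines, which also differ in sex, were compared in vehicle to ask how mt cells differ from wt cells before any ligand. The mt cells had more Ltbp1, which encodes a latent TGF-beta binding protein (3.03 ± 0.27, adjusted p = 0.00013), more of the growth factor gene Fgf10 (4.76 ± 0.58) and of Il6 (3.65 ± 0.51), and more of the endoglin gene Eng (1.52 ± 0.32). They had less of the actin-binding gene Synpo2 (-2.14 ± 0.29), of the homeobox genes Hlx (-4.55 ± 0.48) and Hoxb2 (-3.38 ± 0.39), and of Aldh1a2, the retinoic acid synthesis enzyme (-1.56 ± 0.36). In all 602 genes differed (412 higher in mt, 190 lower), 1739 in the blocked test and 1014 with DESeq2. The count fell to 114 without wt vehicle replicate 2, to 133 without the mt replicate 1 libraries and to 28 with only the 2 vehicle groups in the fit.

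Further large differences in vehicle were Ctnnd2 (5.87 ± 0.79), the angiopoietin-like gene Angptl4 (5.19 ± 0.75), Dscaml1 (5.12 ± 0.77) and the desmosome gene Dsp (5.02 ± 0.85) on the higher side and Sorbs2 (-4.51 ± 0.68) on the lower. Cpne7 and Fzd10 had 2 and 3 reads in wt vehicle, and their mt to wt ratios were 73.3 (95% counting interval 19.7 to 614) and 38.3 (12.6 to 190). Cpne7 was at 6.37 and 0.592 CPM in mt vehicle (replicates 1 and 2) and Fzd10 at 4.14 and 1.02, and without mt vehicle replicate 1 their log2 fold changes were 3.7 (adjusted p = 0.29) and 3.98 (adjusted p = 0.027). Without that library Ctnnd2 was at 4.83, Angptl4 at 3.54, Dscaml1 at 4.11 and Dsp at 3.63, each still called; Col18a1 was at 1.78, Col5a3 at 1.56, Perp at 1.86 and Inhba at 1.53, still called, and Gdf15 at 0.97 (adjusted p = 0.58). H2-Q2 was lower as well (-3.97 ± 0.63); it belongs to a family of near-identical genes, so its reads cannot be assigned with certainty. Of 24 collagens 7 were higher and 0 lower (11 and 1 adjusted over the list alone, 12 and 0 in the blocked test), with Col18a1 at 2.5 ± 0.37, Col5a3 at 2.34 ± 0.39 and Col8a1 at 1.67 ± 0.31, and a list adjusted p of 3.8e-06 (adjusted p = 0.37 with an estimated correlation). Of 30 p53 targets 3 were higher (8 adjusted over the list alone, 10 in the blocked test): Perp (2.66 ± 0.43), Eda2r (1.13 ± 0.23) and the stress cytokine gene Gdf15 (2.11 ± 0.52), with a list adjusted p of 2.3e-07 (adjusted p = 0.37 with an estimated correlation). Of 25 cholesterol synthesis genes 0 passed over all genes and 3 were lower adjusted over the list alone, and 10 in the blocked test; Sqle was at -0.87 ± 0.24 (adjusted p = 0.08, blocked 0.022), and the list adjusted p was 3.8e-07 (adjusted p = 0.053 with an estimated correlation). Of 37 ligands, receptors and inhibitors of the family, 5 were higher and 1 lower (8 and 2 adjusted over the list alone, 9 and 2 in the blocked test), among them Inhba (2.36 ± 0.39), Bmpr1b (2.08 ± 0.35) and Acvr1b (-1.58 ± 0.21), with a list adjusted p of 0.014 (adjusted p = 0.47 with an estimated correlation).

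Averaged over the 4 treatments, with 8 libraries per line, mt cells had more Bcat1, a branched-chain amino acid transaminase gene (3.68 ± 0.19), more Ctnnd2 (5.47 ± 0.38), Fgf10 (4.64 ± 0.30), Ppp1r16b (3.48 ± 0.21) and Ltbp1 (2.09 ± 0.13). They had less Pcdh17 (-3.49 ± 0.18), Serpinb6b (-3.83 ± 0.38), the calcification inhibitor Mgp (-3.83 ± 0.67), Saa3 (-3.58 ± 0.44), Tek (-2.57 ± 0.14) and Pdgfra (-2.45 ± 0.28), and Tgfbr3 was at -2.25 ± 0.16 (adjusted p = 3e-06). In all 3030 genes differed (1655 higher in mt, 1375 lower), and 5742 in the blocked test. Of the called genes, 3029 had the same sign in both replicate numbers. Without the mt replicate 1 libraries, which leaves 1 library in each mt group, a part of the 3030 genes lost the call and other genes gained one. Of 28 epicardial genes 3 were higher and 12 lower (4 and 14 adjusted over the list alone), including Clu (-1.43 ± 0.15), Lrrn4 (-1.56 ± 0.17), C3 (-1.39 ± 0.18) and Gata6 (-0.79 ± 0.11), with a list adjusted p of 0.0033 (adjusted p = 0.66 with an estimated correlation). Of 24 collagens 9 were higher and 1 lower (10 and 1 adjusted over the list alone), such as Col4a3 (2.12 ± 0.23), with a list adjusted p of 0.0062 (adjusted p = 0.71 with an estimated correlation).

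Some line differences followed chromosomes or single libraries. Genes of chromosome 8 with at least 5 CPM (682 genes) had a median mt minus wt log2 difference of 0.28, a 1.21-fold level, while medians of the other autosomes ran from -0.06 to 0.06. Of these 682 genes, 190 were called in the average over treatments (170 higher in mt, 20 lower). Xist, transcribed from the inactive X chromosome, was at 258 to 516 CPM in mt libraries and had 0 to 3 reads in wt libraries. Xist was named after its values were seen. The Y-linked Ddx3y was 1 of the 6 largest falls in vehicle. It was at 19.7 to 23.6 CPM in wt libraries and had 0 to 1 reads in mt libraries. By these genes the mt line was female and the wt line male, so every comparison of the lines is also one of sex. Within 10 Mb of Tgfbr3, 45 of 192 genes were called (23.4%) against 17.9% elsewhere (Fisher's exact test, two-sided p = 0.058).

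**Figure D3:**
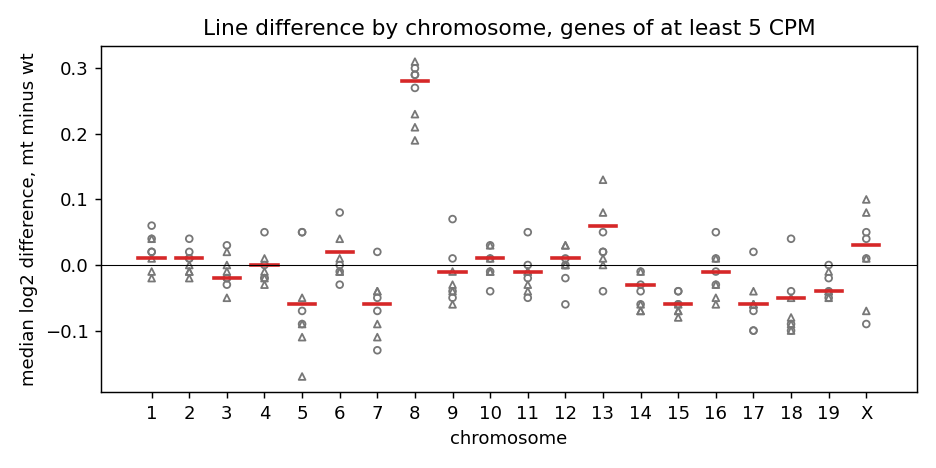
Median log2 difference, mt minus wt, of genes with at least 5 CPM for each chromosome; red bars are the average over treatments and grey symbols the 8 same-numbered comparisons (circles replicate 1, triangles replicate 2). Chromosome 8 lies between 0.19 and 0.31 in the 8 comparisons and above every other autosome in each.

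Cardiomyocyte markers were higher in the average over treatments (10 of 21 higher and 1 lower, 12 and 1 adjusted over the list alone), with a list adjusted p of 0.039 (adjusted p = 0.77 with an estimated correlation). Of 22 such markers in the files, 11 were higher in each of the 4 mt replicate 1 libraries than in any other library. The cardiac myosin gene Myh6 stood at 14.7 to 28.8 rpm there and at most 0.407 rpm in the other 12 libraries, Myh7 at 9.24 to 18.6 against at most 0.471, Myl2 at 7.58 to 19.8 against at most 0.339, and Actc1 at 8.49 to 13.9 against at most 0.936. The troponin gene Tnnt2 was expressed in all libraries and was lower in mt cells (-1.82 ± 0.20).

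**Figure D4:**
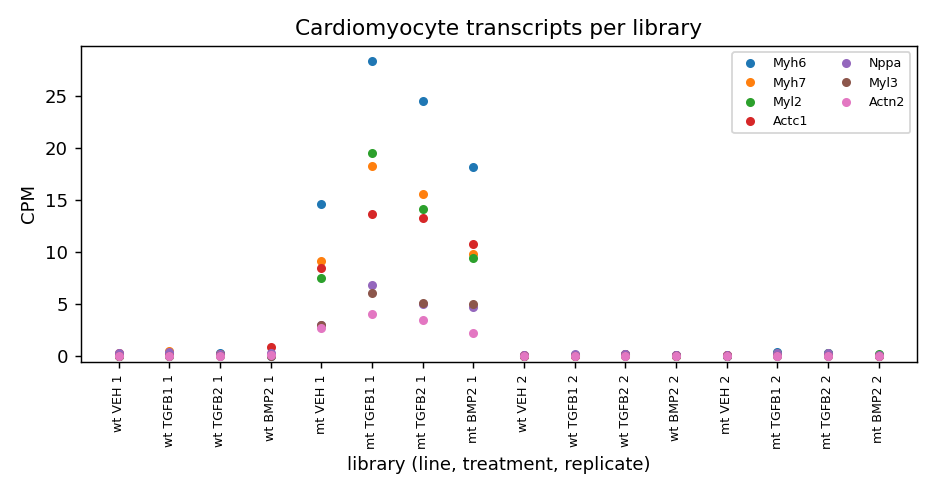
TMM-scaled CPM of 7 cardiomyocyte genes in each of the 16 libraries, replicate 1 on the left and replicate 2 on the right. The 4 mt replicate 1 libraries hold all 7 transcripts, and the other 12 libraries are all below 1 CPM for each.

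The interaction tests asked whether a ligand's effect differed between the lines. Wisp1, a matricellular gene also listed as Elm1 at the same locus (chromosome 15, 66722954 to 66754761), rose less in mt cells. In wt cells Elm1 went from 10.4 ± 1.46 CPM (SD, n = 2) in vehicle to 620 ± 29.7 with TGFB1 and 775 ± 14.3 with TGFB2, and in mt cells from 81.3 ± 3.37 to 563 ± 185 and 563 ± 64.3. The difference was -3.10 ± 0.39 for TGFB1 (adjusted p = 0.03) and -3.42 ± 0.39 for TGFB2 (adjusted p = 0.011). For TGFB2 the kinase gene Dapk2 (-3.56 ± 0.45, adjusted p = 0.024) and Klhl30 (-2.92 ± 0.40, 0.041) rose in wt cells, from 1.37 ± 0.221 to 66.8 ± 14.3 CPM and from 7.43 ± 0.745 to 42.3 ± 10.8. In mt cells Dapk2 went from 7.98 ± 1.93 to 32.6 ± 4.6 CPM and Klhl30 from 11.2 ± 2.93 to 8.34 ± 0.865.

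The cyclin D1 gene Ccnd1 had a more negative TGFB2 effect in mt than in wt cells (-2.87 ± 0.41, adjusted p = 0.041). In mt cells it went from 357 ± 167 CPM (SD, n = 2) to 22.8 ± 2.86, and in wt cells from 84.0 ± 11.1 to 39.1 ± 5.3. Amdhd1 (-3.54 ± 0.50) went from 10.4 ± 0.0301 to 0.701 ± 0.0174 CPM in mt cells and from 8.66 ± 2.88 to 6.88 ± 2.01 in wt cells, and Clca2 (-2.68 ± 0.40) from 16.7 and 11.8 CPM to 2.14 and 3.57 in mt cells (replicates 1 and 2) and from 13.0 ± 0.592 to 17.1 ± 2.26 in wt cells. Pbp2 (-4.31 ± 0.63, adjusted p = 0.041) falls outside the naming rule by its low level and was named after its value was seen. The TGFB1 test called 2 entries, both at the Wisp1 locus, and the TGFB2 test 8 entries at 7 loci. Each had a less positive or more negative log2 effect in mt cells. Wisp1 and Dapk2 thus rose less in mt cells, while Ccnd1, Amdhd1 and Clca2 had the larger change there, a fall.

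**Figure D5:**
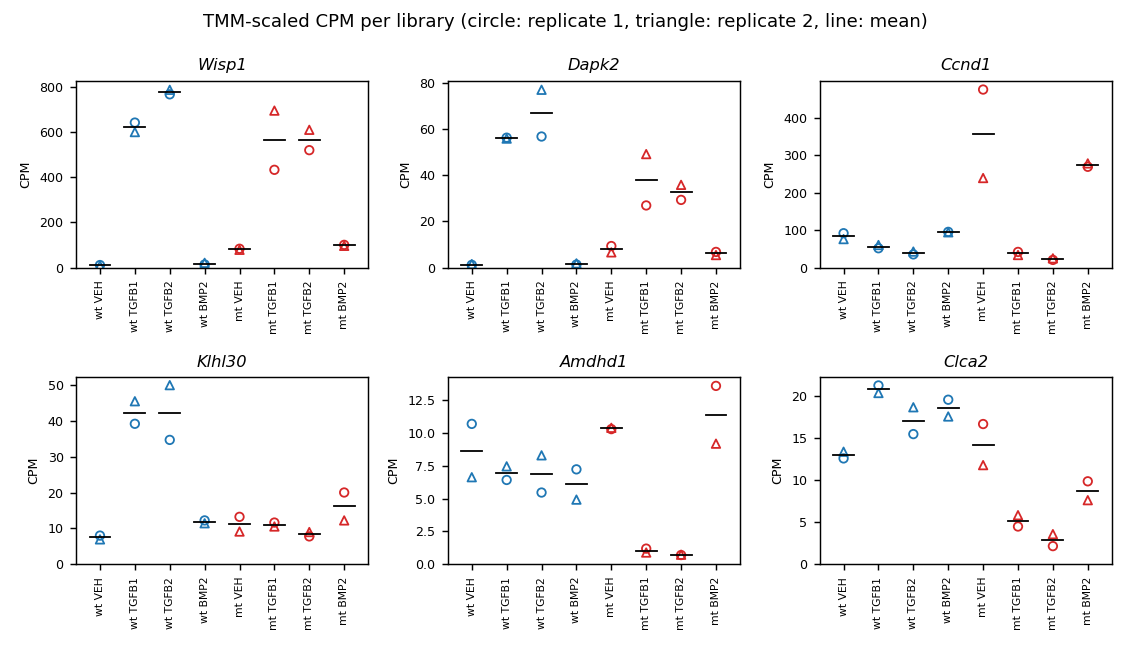
TMM-scaled CPM of 6 genes called in the interaction with TGFB2, per library on a linear axis from 0 (wt blue, mt red); circles are replicate 1, triangles replicate 2, and bars the mean of the 2. Wisp1 and Dapk2 start higher in mt vehicle and end lower with TGFB2 than in wt cells, and Ccnd1 starts at 357 CPM in mt vehicle against 84.0 in wt.

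The blocked test called 138 entries for the TGFB1 interaction (20 higher, 118 lower) and 143 for TGFB2 (18 higher, 125 lower), and DESeq2 111 and 141. With only the groups compared, and without the mt replicate 1 libraries, both counts were 0. Leaving out 1 library gave 0 to 35 entries for TGFB1 (35 without mt vehicle replicate 2) and 0 to 27 for TGFB2 (27 without mt vehicle replicate 2). The Wisp1 value stayed between -3.48 and -2.80 for TGFB1 in those fits, where Elm1 lost its call in 6 of 8 and reached an adjusted p of 0.44 without wt vehicle replicate 2. For BMP2 the edgeR test called 0 genes (543 at an unadjusted p under 0.05; blocked 0 with 1862; DESeq2 2). Of 50 simulated genes whose effect differed 4-fold between lines, 15 were recovered for TGFB1, 23 for TGFB2 and 15 for BMP2.

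By list, 24 collagens had a median interaction of -0.75 with both TGFB1 and TGFB2 (0 members called over all genes and 0 adjusted over the list alone). Their adjusted p was 2.8e-05 for TGFB1 (adjusted p = 0.42 with an estimated correlation) and 4.8e-05 for TGFB2 (adjusted p = 0.31 with an estimated correlation). The 30 p53 targets had medians of -0.56 and -0.65 and the 30 mitotic genes of 0.41 and 0.50, again with 0 members called by either adjustment, over all genes and adjusted over the list alone (in the blocked test 1 p53 target for each ligand). For p53 the adjusted p was 2.8e-05 for TGFB1 (adjusted p = 0.42 with an estimated correlation) and 8.7e-08 for TGFB2 (adjusted p = 0.19 with an estimated correlation), and for mitosis 0.00059 (adjusted p = 0.56 with an estimated correlation) and 3.9e-06 (adjusted p = 0.31 with an estimated correlation). Each interaction contains the line difference in vehicle with the opposite sign. In vehicle the medians were 0.76 for collagens, 0.65 for p53 targets and -0.17 for mitotic genes. Part of these interactions may thus come from the vehicle libraries. Over all comparisons 101 list tests passed with the preset correlation and 6 with an estimated one. The 6 were epicardial genes for TGFB2 in wt and both TGF-beta ligands in mt cells, SMAD3 targets for TGFB2 in wt and BMP2 in mt cells, and BMP targets for BMP2 in mt cells.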

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

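The tests of the explanations given here were chosen after the results were seen; the tests of the interactions themselves were planned.

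A first set of results drew attention because a ligand's effect differed between the lines in the interaction test. For TGFB1 the gene was Wisp1, also listed as Elm1 (-3.10). For TGFB2 the genes were Wisp1 (-3.42), Dapk2 (-3.56), Amdhd1 (-3.54), Ccnd1 (-2.87), Clca2 (-2.68), Klhl30 (-2.92) and Pbp2 (-4.31), each a log2 difference of the mt effect from the wt effect, with 2 libraries per group. Without the 4 mt replicate 1 libraries 0 genes were called for either ligand, with 1 library left in each mt group. The values kept their sign: Wisp1 went from -3.10 ± 0.39 to -2.75 ± 0.46 for TGFB1 (SE; adjusted p from 0.03 to 0.83). For TGFB2 the values were Wisp1 -3.26 ± 0.46, Dapk2 -3.16 ± 0.43, Amdhd1 -3.53 ± 0.66, Ccnd1 -2.17 ± 0.37, Clca2 -2.12 ± 0.38, Klhl30 -2.53 ± 0.43 and Pbp2 -3.90 ± 0.81 (adjusted p 0.45 to 0.70). This fit has 12 libraries and 4 residual degrees of freedom in place of 8, so the lost calls alone do not single out the libraries left out.

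Gene lists drew attention by the same kind of test, as medians of the log2 interaction. With TGFB1 and TGFB2 respectively these were collagens (-0.75 and -0.75), matrix glycoproteins (-0.68 and -0.65), hyaluronan and remodelling genes (-0.52 and -0.71), epithelial junction genes (-0.67 and -0.50), epicardial genes (-0.44 and -0.42), p53 targets (-0.56 and -0.65), growth factor signalling genes of the FGF, PDGF, VEGF and HGF families (-0.47 and -0.55), Wnt and Notch genes (-0.45 and -0.67), interferon-stimulated genes (-0.30 and -0.27), mitotic genes (0.41 and 0.50), cholesterol synthesis genes (0.44 and 0.48) and immediate early genes (0.40 and 0.19). With TGFB2 they also included SMAD3 targets (-0.44), ligands and receptors of the family (-0.24) and unfolded protein response genes (-0.30). With TGFB1 these lists had medians of -0.37, -0.20 and -0.20 (list test adjusted p = 0.31, 0.064 and 0.13). The ligands and receptors had a blocked adjusted p of 0.029 with TGFB1. Whether the interaction differs between the ligands was not tested. With BMP2 they were BMP targets (0.39), YAP and SRF targets (-0.44) and immediate early genes (-0.48). The line difference in vehicle enters each interaction with the opposite sign. Its medians were 0.76 for collagens, 0.65 for p53 targets and -0.64 for cholesterol synthesis genes. Only epicardial genes (-0.16) and, for BMP2, immediate early genes (-0.4) had the same sign in vehicle as in the interaction. Part of the other medians may thus come from the vehicle libraries. None of these interaction lists passed with an estimated correlation. The lowest adjusted p was then 0.12, with TGFB2, for the hyaluronan and remodelling, growth factor and cholesterol synthesis lists.

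Genes of chromosome 8 stood higher in the mt line. The median log2 difference was 0.28, and each of the 20 Mb bins along the chromosome was raised, the lowest bin by 0.23 against at most 0.06 for the medians of other autosomes. A few strongly changed genes would leave the rest unmoved, yet 85.2% of its 682 genes lay above the median of the other autosomes (95% interval 82.3 to 87.8, Clopper-Pearson). The interval treats genes as independent, which they are not, and does not cover the spread between lines. A deviation of 1 treatment or 1 replicate number is argued against by the chromosome's highest rank among autosomes in 8 of 8 same-numbered comparisons. The values are consistent with a higher relative dose of the whole chromosome, in all or a part of the mt cells, or a lower one in wt cells; DNA was not measured in the files used, and with 1 line per genotype a link to Tgfbr3 is untested.

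Cardiomyocyte transcripts in the 4 mt replicate 1 libraries formed another pattern. Myh6 was at 14.7 to 28.8 rpm there and at most 0.407 rpm in the mt replicate 2 libraries. Of 22 marker genes in the files 11 were above every other library in all 4, while Tnnt2 and Hand2 were expressed throughout by both lines. The 7 genes at over 1 rpm in these libraries and under 1 rpm in the other 12 (Myh6, Myh7, Actc1, Actn2, Nppa, Myl2 and Myl3) summed to 48.7 to 98.3 rpm and moved together: the median SD of their log2 levels over the 4 libraries fell from 0.45 to 0.16 after each library was centred on their mean. This is consistent with 1 source of cardiomyocyte cells, RNA or reads shared by the 4 libraries, and which of these it was stays open; a difference in state between the cultures of the 2 numbers was not tested. Globin reads were not confined to the mt line: in the 8 replicate 1 libraries, wt ones included, Hba-a2 was at 1.23 to 14.5 rpm and Hbb-b1 at 0.18 to 1.65 rpm, against at most 0.129 and 0.108 rpm in the replicate 2 libraries. Other markers overlapped between the numbers: the endothelial gene Cdh5 was at 0.0914 to 1.35 rpm against at most 0.102, Pecam1 at 0 to 0.706 against at most 0.204, and the leukocyte gene Ptprc at 0 to 0.224 against at most 0.0629. For Cdh5 the overlap came from wt vehicle replicate 1 alone (0.0914 rpm), and every other replicate 1 library was at 0.24 rpm or more. Whether the globin reads share a source with the cardiomyocyte transcripts was not tested.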

How the results depend on the processing

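The alternatives named as added were chosen after the data were seen; the others were planned. Of the counts of genes or of passed list tests recomputed, 110 stayed within 1.5 times their value and 67 did not. A count that stayed within 1.5 times can still be made up of partly different genes. No gene called by the main fit and by an alternative changed direction between the 2. Of the named gene values, 13979 kept their direction and side of the threshold, 571 lost a call (545 with a library left out), 205 gained one and 267 changed direction with a call in neither fit; of the list tests 3254 kept both, 228 lost a call, 160 gained one, 297 changed direction with a call in neither fit and 9 with a call in at least 1 of the fits. The values and list tests that kept both include those called in neither fit. With the replicate block, for instance, 753 named gene values stayed without a call and 666 kept one. Leaving out a library leaves a lone sample in its group, which is assumed to vary like the other groups. For the low counts with fewer samples or with the compared groups alone, fewer residual degrees of freedom are part of the construction. With the compared groups alone, TGFB1 and TGFB2 in wt cells still called 3258 and 3552 genes, against 297 and 1064 in mt cells. Fewer residual degrees of freedom alone thus do not account for these low mt counts. For all other changes the cause was not tested. With RLE size factors every count of genes stayed within 1.5 times.

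With the replicate number as a term, counts were 1739 for the lines in vehicle and 5742 averaged over treatments, 5630 for TGFB1 and 5837 for TGFB2 in wt cells, 5472 and 5641 in mt cells, 39 for BMP2 in mt cells, 138 and 143 for the interactions with TGFB1 and TGFB2, and 4836 (wt) and 4924 (mt) for genes shared by the TGF-beta ligands. With the DESeq2 Wald test they were 1014 for the lines in vehicle, 14 for BMP2 in wt and 47 in mt cells, and 111, 141 and 2 for the interactions with TGFB1, TGFB2 and BMP2. With no filter on low counts they were 19 for BMP2 in mt cells and 25 and 48 for the interactions with TGFB1 and TGFB2. With the compared groups only they were 28 for the lines in vehicle, 297 for TGFB1 and 1064 for TGFB2 in mt cells, 0 for BMP2 in mt cells, and 0 and 0 for the interactions with TGFB1 and TGFB2. Without the 4 mt replicate 1 libraries (added) they were 133 for the lines in vehicle, 1594, 1637 and 0 for TGFB1, TGFB2 and BMP2 in mt cells, and 0 and 0 for the interactions with TGFB1 and TGFB2. With entries that share a locus counted once (added), the TGFB1 interaction had 1. With an estimated correlation 6 list tests passed, in place of 101.

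With 1 library left out, counts ranged from 114 to 897 for the lines in vehicle, 1575 to 1906 for TGFB1 and 1775 to 2087 for TGFB2 in wt cells, 1198 to 2549 and 1325 to 2674 in mt cells, 0 to 2 for BMP2 in mt cells, and 0 to 35 and 0 to 27 for the interactions with TGFB1 and TGFB2. For BMP2 in wt cells, the BMP2 interaction and TGFB2 against TGFB1, edgeR called 0 genes in each of these fits.

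The list tests that changed direction with a call in either fit are given as adjusted p, with a minus sign where the list pointed down. A signed range over the fits with 1 library left out has weak values at its ends, so the smallest p in the other direction stands beside it. Smooth muscle genes turned for the lines in vehicle without mt vehicle replicate 2 (0.014; range -0.317 to 0.492; -0.00188 without mt vehicle replicate 1) and for the BMP2 interaction without mt vehicle replicate 1 (0.00399; range -0.764 to 0.836; -0.0214 without mt vehicle replicate 2). Mitotic genes turned for BMP2 in wt cells without wt BMP2 replicate 1 (0.0286; range -0.349 to 0.514; -0.133 without wt BMP2 replicate 2). For TGFB2 against TGFB1 in mt cells they turned without mt TGFB2 replicate 1 (-0.000229) or mt TGFB1 replicate 2 (-0.0142), and gave 3.51e-05 and 7.08e-05 without the other 2 libraries. Interferon genes turned for the TGFB2 interaction without wt vehicle replicate 1 (0.849; range -0.832 to 0.849). They kept their call, pointing down, in 3 of the 8 fits (-2.86e-05 without wt vehicle replicate 2, -0.000455 without wt TGFB2 replicate 1 and -0.015 without mt TGFB2 replicate 1). Cardiomyocyte markers turned for the TGFB2 interaction without mt TGFB2 replicate 2 (0.0176; range -0.888 to 0.966; -0.00983 without mt TGFB2 replicate 1). For TGFB2 against TGFB1 in mt cells they turned without mt TGFB1 replicate 1 (0.00036) or mt TGFB2 replicate 2 (0.000365), and gave -8.99e-11 without mt TGFB2 replicate 1 and -3.38e-06 without mt TGFB1 replicate 2.

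Small changes were seldom recovered: in simulated data with 2 libraries per group, 1 to 6 of 50 genes changed 2-fold were recovered for the lines in vehicle and for the ligands, and 33 or more of 50 changed 4-fold.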

Other observations

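Of the tests here, the correlation without a shared library and the comparison across lines were chosen after the results were seen; the test across replicate numbers and that of other splits were planned.

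Of 4 further gene groups, 3 passed the list test with TGFB1 in wt cells with the preset correlation and 0 with an estimated one. Of 17 osteogenic and chondrogenic genes 7 rose and 2 fell (8 and 3 adjusted over the list alone), among them Tnfrsf11b (6.22 ± 0.46), the cartilage collagen gene Col2a1 (3.70 ± 0.75) and Matn3 (3.01 ± 0.52). The list adjusted p was 0.0042 (adjusted p = 0.22 with an estimated correlation). Of 19 retinoic acid pathway genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), with the binding protein genes Crabp1 (5.08 ± 0.39) and Crabp2 (2.77 ± 0.42), the transporter gene Stra6 (2.61 ± 0.50) and the transglutaminase gene Tgm2 (-3.73 ± 0.37); the list adjusted p was 0.14. Of 23 immediate early and stress genes 8 fell and 0 rose (12 and 1 adjusted over the list alone, and also in the blocked test), such as Klf4 (-1.39 ± 0.18) and Zfp36 (-1.24 ± 0.24), with an adjusted p of 0.00085 (adjusted p = 0.24 with an estimated correlation). Of 21 epithelial junction genes 6 rose and 1 fell (10 and 2 adjusted over the list alone, 10 and 3 in the blocked test), including St14 (5.30 ± 0.70) and Dsp (4.73 ± 0.84), with an adjusted p of 0.036 (adjusted p = 0.56 with an estimated correlation). In mt cells Cldn15 fell with TGFB1 (-4.78 ± 0.69), and 4 of the junction genes rose and 3 fell (5 and 4 adjusted over the list alone, 6 and 7 in the blocked test; list test adjusted p = 0.8).

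Growth factor and Notch or Wnt genes went both ways. In wt cells with TGFB1, Pdgfb (2.72 ± 0.31), Pgf (4.18 ± 0.64), Nrp1 (2.03 ± 0.21) and Wnt11 (2.20 ± 0.31) rose and Sfrp2 (-3.68 ± 0.44) and Wnt2b (-2.14 ± 0.45) fell. The list tests gave an adjusted p of 0.15 for the growth factor genes and 0.14 for Wnt and Notch. Of 13 endothelial markers 2 rose and 2 fell with TGFB2 in wt cells (list test adjusted p = 0.52), and 3 rose and 1 fell in mt cells (0.68). Among them Ptprb rose in wt (5.48 ± 0.62) and mt cells (4.87 ± 0.54), while Tek fell in both (-1.45 ± 0.26 and -1.96 ± 0.30).

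A hypothesis was that mt cells without ligand lie part of the way along the wt response to TGFB1 and TGFB2. On PC1 the vehicle libraries of mt cells were at 23.0 and 50.5 and those of wt cells at 84.4 and 93.1. With TGFB1 or TGFB2 the mt libraries were also lower (-84.3 to -74.4) than the wt ones (-44.8 to -30.8). The offset of the lines on PC1 was thus not confined to cells without ligand, and PC1 alone does not bear out the hypothesis. The line difference in vehicle correlated with the wt response at 0.55 across genes, which are not independent replicates. Shared vehicle libraries as the whole source are argued against by a correlation of 0.48 with the line difference taken from the BMP2 libraries, where 2395 of 2839 genes called for both ligands in wt (84.4%) differed in the direction of the TGFB response. The pairing by replicate number is argued against by the lower cross-number correlation of 0.37. The pattern may belong to this mt line rather than to the loss of Tgfbr3: with 1 line per genotype these cannot be told apart.

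The line difference averaged over treatments was set against other splits of the 16 libraries into 8 and 8 within treatments. The 100 splits compared, of 648 possible, were the real one, the split by replicate number and random ones. Of these, 2 called as many genes as the real one (3030), itself included. The other of the 2 was the split by replicate number, which called 4745, a sign of the structure that the replicate numbers give these libraries. Random splits called at most 840. Most of them mix the lines within a side, so the line difference adds to their spread. Their low counts therefore cannot exclude chance assignment of libraries. With the replicate number in the fit the line difference was 5742 genes. Among the 23 splits that part all 8 pairs, the real one included, the highest other called 795; 85 of the splits called 0 genes by edgeR.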
